A study of Drosophila melanogaster with 2 samples.

How the data were processed

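Binding of Tailless, the nuclear receptor encoded by tll, was measured by ChIP-seq with an antibody to GFP in whole Drosophila melanogaster embryos of both sexes aged 0 to 4 h. The embryos came from a transgenic strain carrying a GFP tag at the C terminus of Tailless, and chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. The samples formed 1 group of 2 biological replicates, numbered 1 and 3 in the labels. Control samples were not analysed here, so each value rests on the comparison with a control that is already inside the deposited peak calls.

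The authors deposited 4 peak lists in dm6 coordinates: 1 for each replicate, 1 for the replicates pooled and 1 list of peaks past an irreproducible discovery rate (IDR) threshold, which measures how far ranked peaks recur between replicates. Per the file headers and accompanying text, each replicate list was derived from the alignment of that replicate and 1 control alignment, the same for both, and the pooled list from both alignments and the control. The aligner, the peak caller, the IDR threshold and their versions are not given in the sources used here. The deposited signal value of each entry is the enrichment the authors' peak caller gave it, on a scale that is not stated, and it was used to rank and describe entries. The deposited −log10 q-value reached a ceiling within every list (4.26 for the pooled and thresholded lists) and was not used to rank. The deposited summit offset gave the position of each summit inside its interval, and entries that shared an interval were kept as separate summits. Read counts were not part of the lists, so the depth of each sample is unknown, and the replicate and pooled lists each held exactly 30000 entries, a length that limits what lies below them. Intervals on shares are exact binomial 95% intervals and cover counting error only, since neighbouring summits are not independent.

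Everything after the peak lists was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. Gene positions came from Ensembl release 115 (BDGP6.54) and sequence from the Release 6 assembly of Drosophila, the same assembly as dm6. The 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X held all entries. Replicates were compared through the 4045 strongest summits of each list, the length of the thresholded list, with an overlap of at least 1 bp counted as shared and 100 circular shifts along the arms as the chance level. Signal values of the replicates were compared at the thresholded summits by Pearson correlation of log10 values and Spearman correlation, with bootstrap intervals from 1000 draws of summits. Each value was that of the strongest entry in the replicate list that overlapped the summit's interval. The 617 thresholded summits that shared an interval therefore carried the same values as the others in it. Summit positions were classed by annotation and by distance to the nearest transcription start site (TSS) of a protein-coding gene, and compared with 1000 circular shifts by two-sided permutation p-values with Benjamini-Hochberg adjustment over 7 classes. Each summit was assigned to the protein-coding gene with the nearest TSS, at most 20 kb away, and a gene with at least 1 such summit is called bound. For 19 gene lists the number of bound members was compared with 10000 random lists drawn from genes in the same of 20 bins of territory length, the length of sequence nearest to the gene's TSS within 20 kb. Those permutation p-values were two-sided and adjusted over the 19 lists. The lists held 427 annotated members, of which 424 had a territory, and 4 symbols were matched through a newer name.

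Words were searched on both strands within 50 bp of the summit and in windows of the same size centred 500 bp to either side. Each of 13 words was tested by a two-sided exact McNemar test of the central window against the window at lower coordinates, adjusted over the 13 words, and the ratio printed is the central share over the mean share of both flanking windows. All 2080 strand-collapsed 6-letter words were ranked by the same ratio, of which 2070 occurred in at least 1% of flanking windows. A trend of word content with signal was tested with a Cochran-Armitage statistic and 100000 permutations. The X chromosome's share of summits was set against its share of sequence by a two-sided exact binomial test.

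The groups, tests, gene lists, words, alternatives and the rule for named genes were fixed before the data were examined. The rule named the nearest gene of the 25 thresholded summits with the highest signal, up to 4 bound members of each list with the strongest summits, the 5 genes with most summits, tll itself and the 5 words with the highest ratio. Alternatives were the 2022 strongest summits alone, each replicate's strongest summits in place of the thresholded list, other distances, windows, flanks and overlaps, and gene bodies with 2 kb around them in place of the nearest TSS. Keeping 1 summit per interval, random lists without matching and X signal values multiplied by 4/3 were added after the data had been seen.

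The procedures were tested on simulated data at the scale of the thresholded list. Of 200 random lists of 10 genes, 2% had a permutation p under 0.05, and of 200 lists of genes with long territories 2.5% did so with matching and 66% without it. Of 200 lists built with 8 of 10 genes bound, 99% passed. Simulated summits lay at random positions and list genes were drawn independently, whereas real summits cluster and real lists hold neighbouring genes. A word planted at 10.5% of random positions raised the central share by 10.04 percentage points and ranked 1 among all words, against rank 678 before planting. A planted overlap of 80.4% was recovered as 81.0%.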

Results

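The data were 4 peak lists from ChIP-seq of GFP-tagged Tailless in embryos of 0 to 4 h, the period in which the anterior-posterior axis is subdivided and gastrulation starts. Tailless is a nuclear receptor of the terminal gap class that acts at both ends of the early embryo. The group held 2 biological replicates, numbered 1 and 3, and no other condition, so the comparisons were between replicates, between summits and chance positions, and between gene groups. Replicates 1 and 3 had 30000 summits each with median signal values of 47.3 and 43.1 and median interval widths of 550 and 480 bp. The thresholded list held 4045 summits in 3725 intervals, with a median signal value of 286.7 and a maximum of 3700. Its members were the 4045 summits of the pooled list with the highest signal, down to 194.6, so it is a list ended by rank. Signal values are the authors' own.

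The replicates were first compared to learn how far separate embryo collections gave the same regions. The summit near prd, a pair-rule gene encoding a homeodomain protein, ranked 1 in replicate 1 and 2 in replicate 3, and the strongest summit assigned to ftz, another pair-rule homeodomain gene, ranked 3 and 5. A stronger summit 21059 bp from ftz, beyond the limit for assignment, ranked 2 and 1. The strongest summit at tll itself ranked 13 and 18. Of the 4045 strongest summits of replicate 1, 3269 (80.8%) overlapped one of the 4045 strongest of replicate 3, and 3117 (77.1%) did so in the reverse direction. After circular shifts the mean overlap was 2.54% and the highest 3.39%, and the one-sided permutation p of 0.0099 is the smallest that 100 shifts can give. Both lists were called against the same control alignment, and the shifts do not measure the recurrence that a shared control gives. Only 16 of the strongest summits of replicate 1 overlapped nothing in the whole list of replicate 3. Across 4039 thresholded summits the signal values of the replicates had a Pearson correlation of r = 0.861 (95% interval 0.850 to 0.870) on the log10 scale and a Spearman correlation of 0.784 (0.768 to 0.798), over summits that were chosen by pooled signal and are not independent replicates. The median ratio of replicate 1 to replicate 3 was 1.11.

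**Figure D1:**
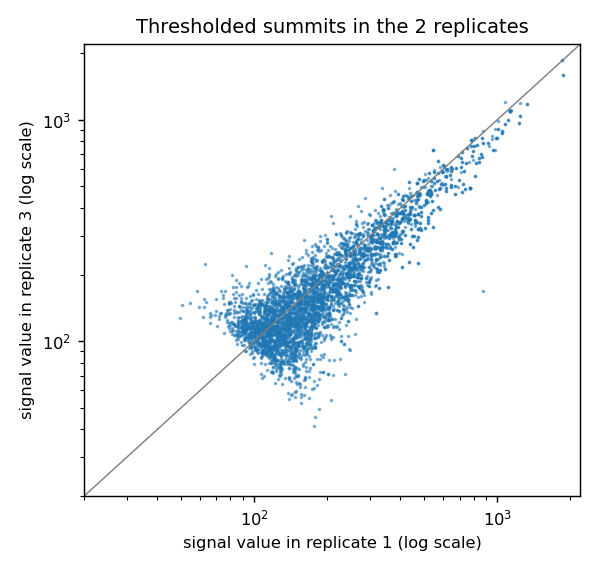
Signal value of the strongest overlapping entry in replicate 1 (x axis, log scale) and replicate 3 (y axis, log scale) for 4039 thresholded summits, with the line of equal values. There is 1 point per summit, and summits that share an interval have the same point. Points follow the line with a correlation of r = 0.861 and spread most at low signal.

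The summits were then described one by one, to name the regions with most signal. The highest, at 3R position 6885383, was intergenic and 21059 bp downstream of the nearest TSS, that of ftz, and had a pooled signal value of 3700. The next lay at prd (2L position 12081257, in a non-coding exon 4121 bp from the TSS, 3460) and at ftz (3R position 6868342, intergenic, 4018 bp from the TSS, 2491). On the log2 scale the replicate signal of the prd summit averaged 10.76 ± 0.16 (SD, n = 2) and that of the ftz summit 10.29 ± 0.12 (SD, n = 2). The summit of rank 9 lay 3582 bp from opa, a pair-rule zinc finger gene, that of rank 13 lay 206 bp from a TSS of pnr, a GATA factor gene of the dorsal embryo, and that of rank 16 lay 2553 bp upstream of tll. The summits of rank 20, 21 and 25 were assigned to the Hox gene Dfd, the Iroquois gene mirr and the head gene cnc.

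Other genes nearest to the 25 strongest summits were tinc, dlp, Sox21b, BigH1, rib and spen. The genes dlp, Sox21b and BigH1 encode a glypican, a Sox transcription factor and the linker histone of the early embryo. The less characterised genes CG42693, CG32986, CG11629, CG13334, CG4702, CG3942, CG6191 and CG45263 were nearest to the rest, apart from the summit of rank 7. That summit was nearest to TER94, which encodes an ATPase, at 2738 bp, and lay 7102 bp from a TSS of the pair-rule gene eve. The summit assigned to CG3942 lay 6056 bp from a TSS of svp, a nuclear receptor gene. A TSS of a fixed-list member lay within 20 kb of 10 of the 25 strongest summits, against 18.6% of the other 4020 (Fisher's exact test, two-sided p = 0.0163). That comparison was chosen after these values were seen, and it left out the ribosomal protein and the odorant and gustatory receptor lists. The genes with most summits were hth, a homeodomain gene, with 15, tna with 13, and Antp, a Hox gene, and opa with 12 each. CG15283, abd-A, ftz and rdx followed with 11 each. Entries that shared an interval were counted separately, and these counts were not scaled to territory length. The gene with the nearest TSS need not be the one regulated, and the 164 summits farther than 20 kb from any TSS were not assigned.

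Fixed gene lists were tested to find which groups of genes had thresholded summits more often than genes with as much flanking sequence. All 7 gap genes and all 10 head gap genes were bound, against means of 2.19 and 3.38 in matched random lists. So were all 8 Hox genes (mean 3.10) and 21 of 22 dorsoventral genes (mean 6.64), all but brk. Of the pair-rule and segment polarity genes 10 of 11 each were bound, without ftz-f1 and gsb-n. With gene bodies and 2 kb around them in place of the nearest TSS, all 11 pair-rule genes and 9 segment polarity genes were bound. The strongest summits of replicate 1 alone gave all 22 dorsoventral genes, and those of replicate 3 alone 20. Odorant and gustatory receptor genes were bound in 2 of 117 cases, below the mean of 18.1. Of the 19 lists, 12 had more bound members than matched lists at an adjusted permutation p under 0.05 and 1 had fewer.

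The gap genes subdivide the embryo into broad domains, and among them tll had 10 summits, kni 8, Kr 7 and gt 3. Close summits were counted separately, as at 3L positions 20697592 and 20697793 near kni. The strongest summit at tll had a log2 replicate signal of 9.90 ± 0.18 (SD, n = 2), at kni 9.30 ± 0.29, at Kr 8.90 ± 0.19 and at gt 8.69 ± 0.21 (adjusted permutation p of the list 0.00095). The tagged gene is tll itself, and extra copies of its region in the transgenic strain may add signal there. The summit of kni lay 1311 bp from its TSS (3L position 20696689, intergenic), that of Kr 1108 bp from its TSS (2R position 25225503, in an intron of CG9380, which overlaps it on the other strand) and that of gt 124 bp from its TSS (X position 2429091, intergenic). Within 20 kb of the genes on either side stood 7 thresholded summits at hb, 7 at Kr, 8 at kni and 4 at gt, loci drawn here after the data had been seen. Head gap genes, which pattern the anterior end, included cnc, ems, croc and slp2 with strongest summits of rank 25, 51, 143 and 186 (adjusted permutation p 0.00076).

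**Figure D2:**
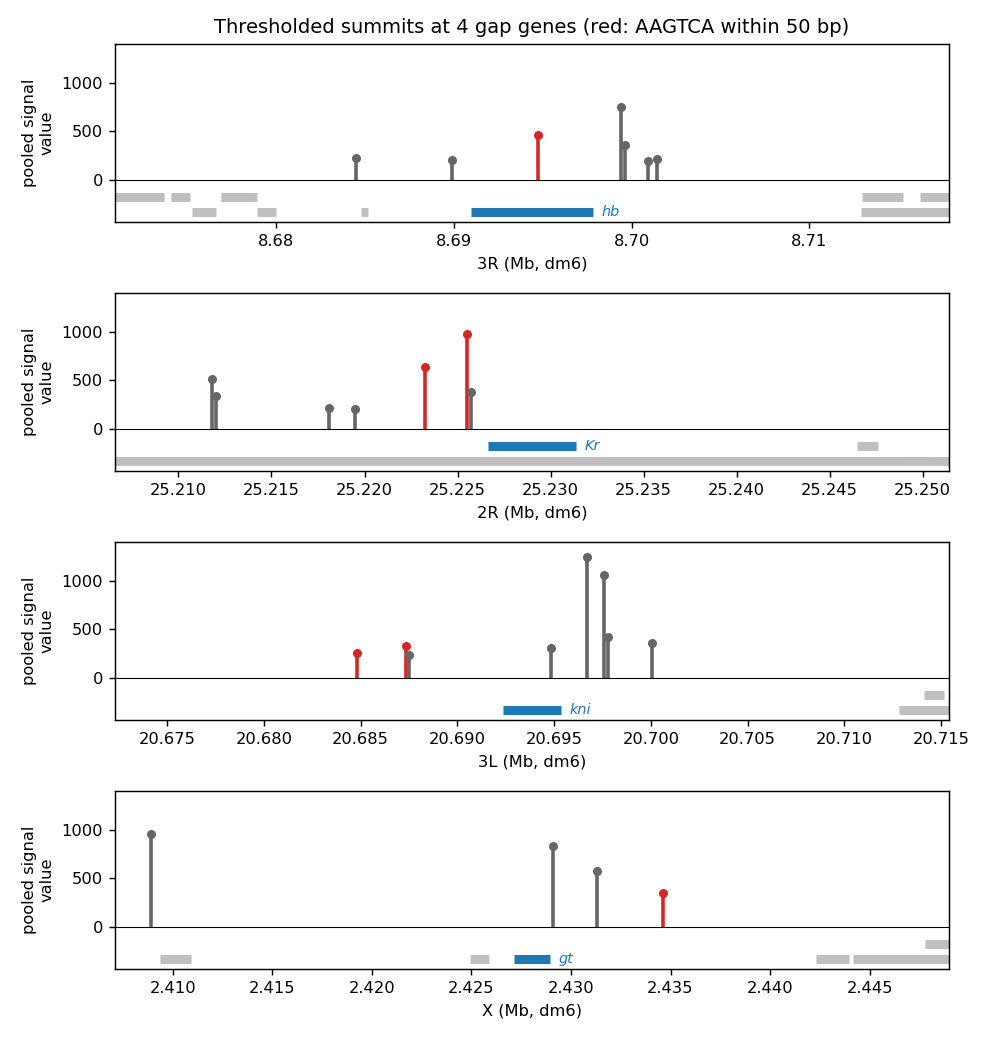
Thresholded summits (vertical lines, height the pooled signal value on the y axis) around hb, Kr, kni and gt, with position in Mb on the x axis, summits with AAGTCA within 50 bp in red, the named gene as a blue bar and other protein-coding genes in grey (upper bars on the plus strand, lower bars on the minus strand). The highest summits shown reach 755.2 at hb, 975.8 at Kr, 1248 at kni and 961.3 near gt.

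Posterior gut genes were bound in 7 of 9 cases against a matched mean of 2.04 (adjusted permutation p 0.0035), among them srp, a GATA factor gene, with rank 65, the homeobox gene cad with rank 296, wntD with 305 and drm with 798. The members byn, a T-box gene of the hindgut, and lin had no thresholded summit. Pair-rule genes (adjusted permutation p 0.00114) were led by prd, ftz and opa, followed by hry, a repressor of the hairy class, with rank 122. Segment polarity genes (adjusted permutation p 0.00095) included en with 8 summits, the T-box genes mid and H15 with 6 and 5, and nkd with 5. Hox genes (adjusted permutation p 0.00138) included Dfd, abd-A, Antp and Abd-B with strongest summits of rank 20, 33, 36 and 38. Dorsoventral genes (adjusted permutation p 0.00076) included pnr, mirr, sim, a regulator of the midline, and dpp, which encodes a BMP ligand, at ranks 13, 21, 27 and 37.

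Genes of the nervous system were bound more often than matched genes as well. Neuroblast genes were bound in 10 of 13 cases (adjusted permutation p 0.00095), including insc, pros, SoxN and sc with strongest summits of rank 132, 173, 320 and 693. Brain and eye genes were bound in 11 of 13 cases (adjusted permutation p 0.00114), including scro with rank 113, the Pax6 genes toy and ey with 645 and 1113, and Vsx1 with 1224. Notch and Enhancer of split genes were bound in 12 of 15 cases against a mean of 2.79 (adjusted permutation p 0.00076), including neur, which encodes a ubiquitin ligase, Brd, E(spl)m5-HLH and Delta with ranks 212, 325, 347 and 360. Early zygotic genes, among the first to be transcribed by the embryo, were bound in 7 of 9 cases (adjusted permutation p 0.00076), including sisA, zld, halo and nullo with ranks 208, 747, 1540 and 1665.

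Torso pathway genes, which signal upstream of tll at the embryo's ends, were bound in 7 of 15 cases against a mean of 3.65 and missed the threshold (adjusted permutation p 0.104). Members with summits included the transcription factor genes aop, cic and pnt and the signalling inhibitor gene sty, with ranks 34, 138, 421 and 962, while tor, trk and tsl had none. Nuclear receptor genes were bound in 9 of 21 cases (adjusted permutation p 0.194), with tll, kni, knrl and EcR in front. The same limit on the signal at tll holds for this list. Ribosomal protein genes were bound in 20 of 92 cases against a mean of 10.9 (adjusted permutation p 0.012), including RpS25, RpS27, RpS19a and RpL7 with ranks 392, 500, 601 and 1095. That call was lost among the 2022 strongest summits, with 7 bound genes (adjusted permutation p 0.725), and against lists without matching (adjusted permutation p 0.199). With gene bodies and 2 kb around them in place of the nearest TSS, 37 were bound against a matched mean of 16.9 (adjusted permutation p 0.000633).

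The remaining lists showed no excess. Muscle structural genes were bound in 2 of 14 cases, Zasp52 and Tm1 (adjusted permutation p 0.576), phototransduction genes in 2 of 14, Rh5 and inaD (1.0), antimicrobial peptide genes in 1 of 14, Def (1.0), and germ plasm genes in 1 of 9, nanos (1.0). These small counts moved with the replicate used: antimicrobial peptide genes had 2 bound members without replicate 1 and 0 without replicate 3, germ plasm genes 0 without replicate 3, and muscle structural genes 1 without replicate 1. The bound receptor genes were Or67d and Or85e (adjusted permutation p 0.00076 for fewer than matched genes). The raw permutation p of the lists at an adjusted 0.00076 was 0.0002, the smallest that 10000 lists can give. Genes of a list can lie side by side and share regions, as in the Hox and Enhancer of split clusters, so members are not independent.

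**Figure D3:**
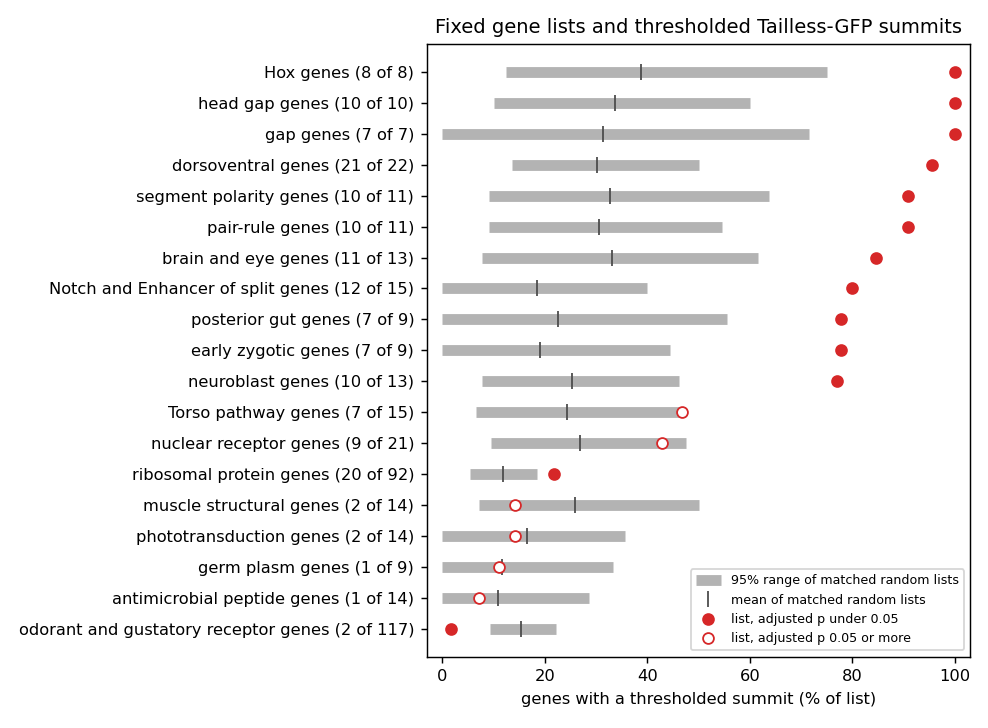
Share of each fixed list with at least 1 thresholded summit (points, x axis in percent of the list) beside the mean (tick) and the 95% range (grey bar) of 10000 random lists matched on territory length, with filled points for an adjusted permutation p under 0.05. Gap, head gap and Hox genes stand at 100%, and odorant and gustatory receptor genes at 1.71%, below their matched range.

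The location of summits was compared with shifted positions to describe where Tailless-GFP signal lay relative to genes. Summits were concentrated at promoters and 5′ UTRs and were rare in coding sequence. Within 500 bp of a TSS lay 1519 of 4045 summits (37.6%), 3.28-fold the shifted mean of 11.5%. Exons of 5′ UTRs held 10.8% against 3.02%, coding sequence 1.53% against 17.0%, 3′ UTRs 1.06% against 4.82%, non-coding exons 3.78% against 1.79% and intergenic sequence 40.9% against 31.0%. Each of these had a permutation p of 0.002, the smallest that 1000 shifts can give, and an adjusted p of 0.00233. Introns held 41.9% against 42.4% after shifts (adjusted permutation p 0.713). The median distance to the nearest TSS was 1447 bp, and 2172 of 13741 protein-coding genes (15.8%) were bound.

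Summits were sparser on the X chromosome than on the autosomes. The X held 446 summits, 18.9 per Mb, against 29.6 per Mb on 2R, 32.9 on 3L, 33.1 on 2L and 34.9 on 3R, and the small chromosome 4 held 30, or 22.3 per Mb. The X share was 11.0% (exact 95% interval 10.1 to 12.0%), against 17.6% of the sequence (exact binomial p = 4.6e-31). With X signal values multiplied by 4/3 before ranking, an alternative added after the data had been seen, the share was 18.6% (17.4 to 19.8%; exact binomial p = 0.103). The X-linked genes gt, sisA, zld and nullo were bound despite the lower density.

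Sequence at the summits was examined for the recognition word of Tailless and for words of other embryonic regulators. The Tailless word AAGTCA lay within 50 bp of 608 of 4045 summits (15.03%, exact 95% interval 13.9 to 16.2%), 3.13-fold the flanking share of 4.80% (exact McNemar test, adjusted p = 1.88e-53). Its longer form AAAGTCA was 4.17-fold as frequent at summits as in the flanks. CAGGTA, the word of the pioneer factor Zelda, was present at 7.24% of summits, 2.64-fold the flanks (exact McNemar test, adjusted p = 7.77e-18). TATCGATA, a core promoter element, was 7.67-fold as frequent but present at 1.71% of summits only. GAGAGA, the word of GAGA factor, and AGGTCA, the site shared by many nuclear receptors, were 1.62-fold and 1.60-fold as frequent as in the flanks (exact McNemar test, adjusted p = 6.9e-08 and 5.36e-05), and CAGCTG 1.35-fold (exact McNemar test, adjusted p = 0.0482). The call of CAGCTG was lost among the 2022 strongest summits (1.25-fold; exact McNemar test, adjusted p = 0.207).

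The words of Bicoid (TAATCC, 1.05-fold), Caudal (TTTATG, 1.07-fold), Snail and Twist (CAGGTG, 1.04-fold, and CATATG, 1.01-fold) and BEAF-32 (CGATA, 1.16-fold) and a bZIP palindrome found at 4 summits did not pass the threshold. Among 2070 words of 6 letters AAGTCA ranked 1, followed by AGTCAA (2.98-fold) and CAGGTA, GAGTCA (2.47-fold) and AGTCAG (2.36-fold), of which AGTCAA, GAGTCA and AGTCAG share 5 letters in a row with it. The median ratio of the other words made of the same letters was 0.925. AAGTCA ranked 2 among the 2022 strongest summits, behind AGTCAA, and 2 in replicate 3 alone, behind CAGGTA. When the summits were divided by signal into 5 parts of 809, the share with AAGTCA fell from 21.0% (18.3 to 24.0%) in the strongest part through 16.9%, 14.7% and 12.9% to 9.64% (7.70 to 11.9%) in the weakest (permutation trend p = 2e-05, the smallest possible). Of the 25 strongest summits 11 had AAGTCA within 50 bp, among them the highest of all and those assigned to opa, Dfd and cnc, while the strongest assigned to prd, ftz and tll had none.

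**Figure D4:**
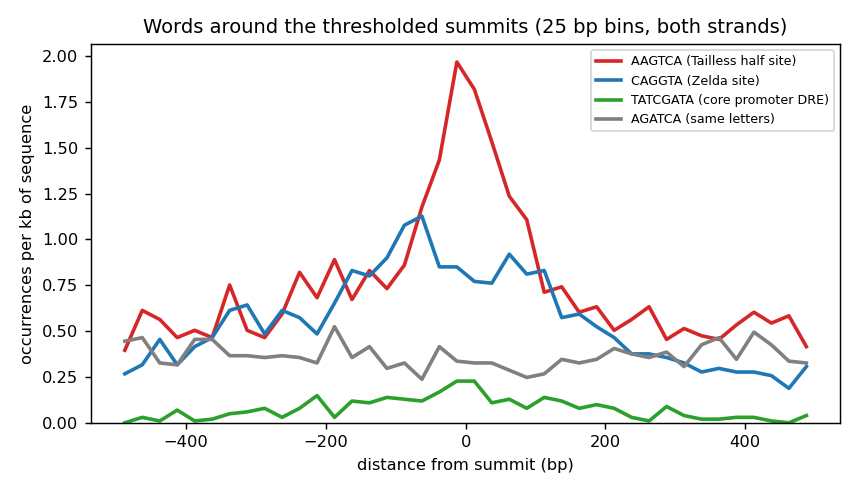
Occurrences of 4 words per kb of sequence (y axis) in bins of 25 bp by distance from the thresholded summits (x axis, bp), both strands counted. AAGTCA reaches 1.97 per kb beside the summit, CAGGTA is highest at 1.13 per kb between 50 and 75 bp away on the side of lower coordinates, TATCGATA is rare, and AGATCA, made of the same letters as AAGTCA, shows no peak.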

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

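All tests in this part beyond the rank among words of the same letters were chosen after the result was seen. The recognition word of Tailless was also concentrated in data outside the thresholded list. Among the 25955 pooled summits below the threshold, AAGTCA lay within 50 bp of 9.09% (exact 95% interval 8.75 to 9.45%) against 4.44% in the flanks, a ratio of 2.05. AAAGTCA had a ratio of 2.61 there, CAGGTA 1.66 and TATCGATA 4.34. Base composition at summits was weighed as a technical source for the thresholded list: AAGTCA ranked 1 of the 120 words made of the same letters, which argues against composition as the whole cause. For the summits below the threshold neither base composition nor any other technical source was tested, and with 1 group no biological explanation was tested.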

How the results depend on the processing

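The alternatives with 1 summit per interval, unmatched random lists and scaled X values were chosen after the data had been seen. Of 311 alternatives, 293 kept the direction and the side of the threshold. The X share rose to 18.6% with X signal values multiplied by 4/3, no longer below the X share of sequence, as that scaling moves X summits up the ranking. The intron share was 44.3% among the 2022 strongest summits, above rather than below its shifted mean, in a class that passed the threshold in neither case. The Spearman correlation of the replicates was 0.811 among the strongest summits. The rank of AAGTCA among 6-letter words was 2 among the strongest summits and ranged from 1 to 2 when either replicate was left out. The cause was not tested for these 3 changes. Replicate overlap ranged from 66.6% with reciprocal overlap of 50% to 83.1% with list length 2022. The share near a TSS ranged from 30.6% within 250 bp to 44.6% within 1000 bp, the AAGTCA ratio from 2.61 to 3.79, and lists with more bound members from 11 to 13. Nuclear receptor genes passed with gene bodies (13 bound, adjusted permutation p 0.0483) and unmatched lists (0.00672), and Torso pathway genes with unmatched lists (0.013). CAGCTG lost its call among the strongest summits (1.25-fold), and TAATCC, TTTATG, CAGGTG, CATATG and CGATA each passed under at least 1 of these alternatives, at 1.15-fold to 1.45-fold. No paired analysis was possible because the samples form 1 group. Depth is unknown, so weaker binding cannot be bounded, and lists of 30000 entries limit what could be compared below them.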

Other observations

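The tests on ribosomal protein and transfer RNA summits, the comparison of promoter summits with the rest, the scaling and list sizes for the X, the comparison of tll with other gap loci and the positions of CAGGTA were chosen only after results had been seen. All 21 ribosomal protein summits lay within 500 bp of a TSS, against 19.8% of the 349 summits of the 7 patterning lists, in which 71 of 76 genes were bound (Fisher's exact test, p = 1.81e-14). That comparison was not matched on territory length, and a gene with a short territory can only hold summits near its TSS. AAGTCA was present at 3 of the 21 and at 62 of the 349 (Fisher's exact test, p = 1.0). Transfer RNA genes had a thresholded summit within 500 bp in 23 of 290 cases, against a mean of 8.84 after shifts and a highest value of 25 (one-sided permutation p = 0.003). Of 32 snRNA and 269 snoRNA genes, 2 and 10 had one (one-sided permutation p = 0.287 and 0.351). Of 99 rRNA genes 0 had one, against a mean of 2.84 after shifts and a highest value of 30. The one-sided permutation p of 1.0 is what any count of 0 gives, so that test cannot decide on rRNA genes.

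Promoter summits differed from the rest in their words. TATCGATA was present at 4.21% of the 1519 summits within 500 bp of a TSS and at 0.198% of the 2526 farther away (Fisher's exact test, adjusted p = 2.02e-21), CGATA at 20.5% and 9.38% (Fisher's exact test, adjusted p = 1.55e-21), and CAGGTA at 5.79% and 8.12% (Fisher's exact test, adjusted p = 0.0126). CGATA is part of TATCGATA, so the 64 summits near a TSS with TATCGATA are among the 311 with CGATA. CAGCTG was present at 7.70% and 4.35% (Fisher's exact test, adjusted p = 4.77e-05). Rarer near a TSS were TTTATG (10.4% and 13.5%), TAATCC (3.42% and 5.34%) and AGGTCA (2.70% and 4.32%; Fisher's exact test, adjusted p = 0.0116, 0.0126 and 0.018). Against the flanks CGATA was 1.71-fold as frequent near a TSS and 0.82-fold farther away (exact McNemar test, adjusted p = 7.99e-08 and 0.0155), TTTATG was 1.24-fold near a TSS (exact McNemar test, adjusted p = 0.0355) and CAGGTG 1.35-fold farther away (exact McNemar test, adjusted p = 0.00558). The flanking share of TTTATG was 8.39% near a TSS and 13.4% farther away. AGGTCA was 1.26-fold near a TSS and 1.77-fold farther away (exact McNemar test, adjusted p = 0.413 and 2.68e-05). The share of summits near a TSS was 26.3% in the strongest of 5 parts of the list and 42.6% in the weakest (permutation trend p = 2e-05, the smallest possible). It was highest in part 4, at 45.4%. The rise did not go on below the list: among the 25955 pooled summits below the threshold 28.5% lay within 500 bp of a TSS, against 11.5% after shifts. The share with AAGTCA among the promoter summits fell with falling signal (permutation trend p = 2e-05), and so did that among the summits farther away (permutation trend p = 0.00724).

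Promoter DNA recovered without Tailless at its word was weighed as a source of the summits near start sites. At those summits AAGTCA was 4.04-fold as frequent as in the flanks, with a share of 14.1% against 15.6% at summits farther away (Fisher's exact test, adjusted p = 0.24). In the strongest of 5 parts of each set the shares were 27.3% and 17.8%, and in the weakest 5.61% and 12.5%, a contrast between the sets that was not tested. The ratio to the flanks argues against such recovery as the whole source, but part of the weaker promoter summits may have come from it, and with 1 group no biological explanation was tested.

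The low number of summits on the X was weighed against copy number and gene content. The X holds 15.7% of protein-coding genes, above the interval of its share of summits (10.1 to 12.0%), so gene content alone does not account for it. Multiplying X signal values by 4/3, the ratio of autosomal to X copies in a population of both sexes, gave an X share of 18.6% (17.4 to 19.8%). That interval holds the 17.6% of sequence, so a single X in males may account for the thresholded list. The interval lies above the 15.7% of protein-coding genes, so the reading depends on the share used for comparison. The factor that equalised the densities was 1.28 (1.24 to 1.34, counting error) for the thresholded list but 1.46 (1.31 to 1.59) for the 500 strongest pooled summits and 1.23 (1.19 to 1.27) for the 12000 strongest, below 4/3, so a constant factor does not cover the longer lists. Control reads, which would carry the same copy number, were not analysed here.

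Zelda words showed no central peak of the kind seen for AAGTCA. Of the CAGGTA occurrences in the 5 bins of 25 bp to either side of a thresholded summit, 36.3% lay within 50 bp, against 53.7% for AAGTCA. CAGGTA stood at 0.808 per kb within 50 bp, at 1.04 per kb in the 3 bins beyond on the side of lower coordinates and at 0.854 per kb in those of higher coordinates (exact binomial p = 0.024 between the sides), so the higher density lay mainly on 1 side. At 133 summits with exactly 1 of each word in these bins, where the summit is equally precise for both, AAGTCA was the nearer in 55.6% (exact 95% interval 46.8 to 64.2%; exact binomial p = 0.225). With so few summits, imprecise summit positions and a different placement of the words cannot be told apart.

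Extra copies of the tll region in the transgenic strain may add signal there: the 20 kb around tll held 49 summits of the replicate lists, above 99.96% of windows. The same width held 42 around kni, 41 around hb, 36 around hkb, 29 around Kr and 17 around gt, the last above 78.7% of windows. The value at tll was the highest of these but within counting error of the next (exact binomial p = 0.53 for tll against kni). A site present in both replicate lists was counted more than once, so that test understates the counting error. Extra copies and dense binding at a gap gene therefore cannot be told apart by this density. Against lists matched for long flanking sequence, 12 lists had more bound members. The matching covered territory length only, not whether a gene was expressed or its DNA accessible in these embryos. For all thresholded summits assigned by the nearest TSS within 20 kb, Torso pathway and nuclear receptor genes passed only when the lists were not matched, and ribosomal protein genes only when they were.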
